A study of Homo sapiens with 2 samples.

How the data were processed

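RNA from 2 samples of AGS cells was sequenced, 1 transfected with an empty vector (control) and 1 with a vector carrying HOXC10, per the labels' protocols. Libraries were made with the TruSeq RNA sample preparation kit, per the labels' protocols. The submitters' processing notes name STAR 2.5.1, edgeR 3.12.1 and genome build hg19, without the role or order of each tool. The gene annotation and the read counter are not given in the sources used here.

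The authors deposited 1 table of log2 values with a row per gene symbol and a column per library, and 0 columns belonged to other samples. The deposited log2 values were log2(CPM + 1), reads per 1000000 reads of a library size with 1 added, which was worked out from the values: raising 2 to each value and subtracting 1 gave whole multiples of 1 step per library. The reads of every gene were recovered by dividing by that step, and 100% of the values in each library came out whole within 0.01 reads. The step implies library sizes of 17543612 reads for the control and 19543666 for the HOXC10 library, of which 85.7% and 87.1% lay in listed genes. Whether the authors scaled these library sizes is not given in the sources used here, and scaling would shift the CPM ratios of all genes alike. The smallest maximum over both libraries of any gene was 1.02 CPM, so genes below about 1 CPM in both libraries are not analysed here. A count of 3 reads corresponds to 0.171 CPM in the control and 0.154 CPM in the HOXC10 library. The top 10 genes took 4.33% and 4.37% of the reads.

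With 1 library per group no test and no p-value was computed, and differences are the deposited HOXC10 value minus the deposited control value. A difference on the log2(CPM + 1) scale understates the difference of low genes, so the ratio of CPM is given for the main genes, with an exact conditional (Clopper-Pearson) 95% interval from the recovered reads. Levels carry exact Poisson 95% intervals. Genes were counted as higher or lower by a rule of size: a log2 difference of at least 1 in either direction and a mean of both CPM values of at least 5. The genes named are HOXC10, CST1, the 12 highest and 12 lowest genes at a mean of at least 5 CPM, up to 4 members of each list with the largest absolute differences at a mean of at least 1 CPM, and any cystatin or HOX gene past 2-fold. Genes of the brain sets and of the CEACAM, PSG, S100A, SNHG, KLK and HOXB families outside that rule were named after their values were seen. Some genes that these rules would name are not reported here.

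For 37 gene lists, the median log2 difference of members with a mean of at least 1 CPM was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5, and 32 lists had the 5 measured members needed. HOXC10 was left out of its list. These percentiles describe the pair of libraries. The groups, the rules of size, the lists, the named-gene rule and 10 alternative settings were fixed before the data were examined. Another 5 settings, the brain sets and the gene families were chosen after.

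Transcript lengths and GC content came from GENCODE release 29 on GRCh38, matched by gene symbol, using the longest protein-coding transcript of each gene, or the longest transcript where none codes. Of the genes with a mean of at least 5 CPM, 9818 (99.4%) had one. Trends were removed with a lowess curve (span 0.3, 3 iterations). For list medians with a length or GC trend removed, the curve was fitted without the members of the list in question. The percentile of the brain sets was obtained in the same way. For the trend with expression level, and for values of single genes and gene families, the curve was fitted on all genes with a mean of at least 1 CPM. A different length measure, the median length of the protein-coding transcripts of each gene, was used as an alternative. No coordinates are printed, because the table gives symbols only and the notes name another build than the reference.

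The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. It was tested on simulated data, drawn for the 11901 genes of the HOXC10 against control comparison. The simulated reads were recovered exactly for 100% of values, and 0 genes simulated without a difference were called. The simulated libraries held counting error only, so false calls from differences between cultures or preparations were not tested. Of 50 genes simulated at each size, 0% were called at 1.5-fold, 50% at 2-fold, 96% at 3-fold and 96% at 4-fold. Of 200 random lists of 25 genes, 7% stood apart, and 99% did after a shift of 0.3 on the log2 scale.

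The alternatives were a median difference set to 0, removal of a trend with expression level, log2(CPM + 1) recomputed, log2(CPM + 5), no filter or a mean of at least 20 CPM, thresholds of 1.5-fold and 3-fold, the mean in place of the median of a list, and percentile limits of 0.5 and 99.5. Added after seeing the data were log2 ratios from recovered reads with 0.5 reads added, removal of trends with transcript length by either length measure or with GC content, and a count of lower genes without the brain sets.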

Results

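The data were 2 RNA-seq libraries of AGS cells, an epithelial line derived from a human gastric adenocarcinoma. The control library came from cells given an empty vector, and the HOXC10 library came from cells given a vector carrying HOXC10, a homeobox transcription factor. Each group had 1 library, so no difference below has a replicate check, no test was run, and the values compare these libraries rather than the conditions. The deposited table held 11901 genes, with 15037332 reads in the control library and 17023393 in the HOXC10 library. The reads of each gene were recovered from the deposited values, and levels are given as CPM, reads per 1000000 reads of library size. A single read stood for 0.0570 CPM in the control library and 0.0512 CPM in the HOXC10 library. The 95% intervals cover counting error only and leave out the spread between replicates. They treat each read as independent, so they are too narrow where PCR reads without molecular identifiers are copies of the same molecule.

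The first comparison asked whether the library labelled as overexpressing carried more HOXC10 RNA. HOXC10 was higher in the HOXC10 library, at 8.80 CPM (172 reads, 95% Poisson interval 7.53 to 10.2 CPM), than in the control library, at 0.0570 CPM (1 read, interval 0.00144 to 0.318 CPM). The ratio of CPM was 154, with a counting interval of 27.3 to 6133 that is wide because the control library held 1 read. On the log2(CPM + 1) scale, which understates the difference of low genes, HOXC10 differed by 3.21. HOXC10 ranked 9070 of the 11901 genes by level in its own library, where the median gene had 30.6 CPM. Reads from the vector and from the chromosomal gene were not separated in these values.

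The title of the series names CST1 beside HOXC10, and the next comparison asked whether its level differed. CST1, which encodes the secreted cysteine protease inhibitor cystatin SN, was higher in the HOXC10 library, at 560 CPM (10946 reads) against 216 CPM (3798 reads) in the control library. The ratio was 2.59 (counting interval 2.49 to 2.69), the log2 difference was 1.37, and CST1 ranked 16 among the 9882 genes with a mean of at least 5 CPM. All 4 cystatins that were measured were higher in the HOXC10 library, and CST1 alone passed 2-fold. CST4, a close copy of CST1, so that the split of reads between them is uncertain, had 5.24 and 10.2 CPM, a ratio of 1.94 (1.51 to 2.51). CST3, the widely expressed cystatin C, had 143 and 197 CPM, and CSTB, an intracellular cystatin, had 109 and 118 CPM. CST1 has a short annotated transcript of 760 nucleotides, and short transcripts were in general higher in the HOXC10 library, as described below.

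**Figure D1:**
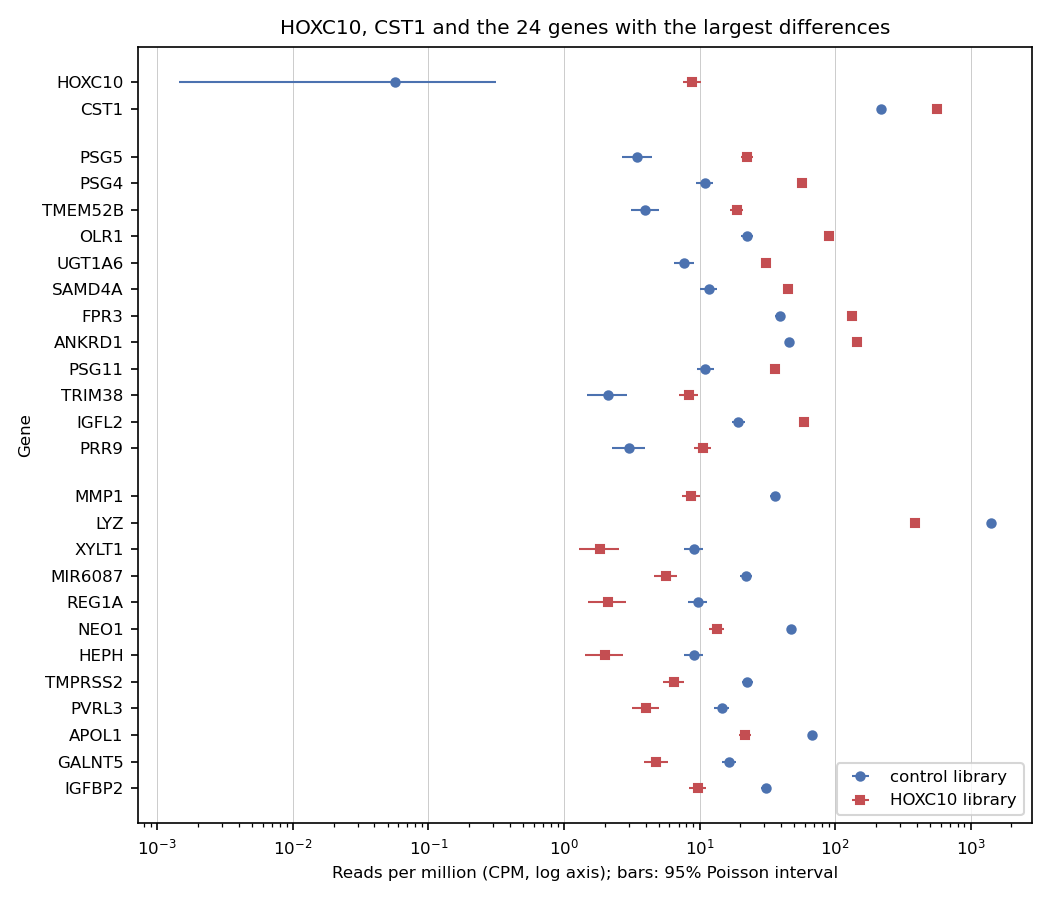
Levels of HOXC10, CST1 and the 12 highest and 12 lowest genes in CPM (log axis), 1 point per library, with 95% Poisson intervals as bars. HOXC10 lies at 0.0570 CPM in the control library and 8.80 CPM in the HOXC10 library, and CST1 at 216 and 560 CPM.

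Across the transcriptome few genes differed by 2-fold or more. Ranked on the log2(CPM + 1) scale, pregnancy-specific glycoprotein genes led the higher side: PSG5 had 3.48 CPM in the control and 22.4 CPM in the HOXC10 library, a ratio of 6.45 (4.92 to 8.57), and PSG4 had 10.9 and 57.2 CPM, a ratio of 5.25 (4.50 to 6.16). The collagenase MMP1, at 36.1 and 8.70 CPM, and lysozyme, LYZ, at 1403 and 386 CPM, led the lower side on that scale, with CPM ratios of 0.241 (0.202 to 0.286) and 0.275 (0.268 to 0.282). Of the 9882 genes with a mean of at least 5 CPM, 26 (0.263%) were at least 2-fold higher in the HOXC10 library and 52 (0.526%) were at least 2-fold lower. The counting interval of the ratio left out 1 for all 78 of these genes, which the rule of size makes all but certain at these depths. Of the 9882 genes, 9385 lay within 1.5-fold. HOXC10 itself is not among the 26 genes, because its mean lay below 5 CPM.

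After PSG5 and PSG4, the next genes on the higher side by log2(CPM + 1) were TMEM52B (3.99 and 18.8 CPM), the oxidised lipoprotein receptor OLR1 (22.4 and 89.6 CPM), UGT1A6, which shares exons with other UGT1A glucuronosyltransferases (7.70 and 30.9 CPM), and SAMD4A, an RNA-binding repressor of translation (11.7 and 44.8 CPM). Their log2 differences ran from 1.85 for SAMD4A to 1.99 for TMEM52B. The formyl peptide receptor FPR3 (39.0 and 134 CPM), the ankyrin repeat protein ANKRD1 (46.1 and 146 CPM), PSG11 (11.1 and 36.2 CPM), the ubiquitin ligase TRIM38 (2.11 and 8.34 CPM), IGFL2 (19.3 and 58.7 CPM) and PRR9 (3.02 and 10.5 CPM) completed the 12 highest, with log2 differences from 1.52 for PRR9 to 1.75 for FPR3. PSG genes are near-identical copies, so how the reads were shared among PSG4, PSG5 and PSG11 is uncertain, but all 7 listed PSG genes were higher in the HOXC10 library.

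On the lower side, where XYLT1, REG1A and HEPH had lower CPM ratios than MMP1 (0.203, 0.216 and 0.220), XYLT1, which starts glycosaminoglycan chains, had 9.06 and 1.84 CPM, the secreted protein gene REG1A 9.69 and 2.10 CPM, and the microRNA locus MIR6087 21.9 and 5.63 CPM. MIR6087 is annotated at 49 nucleotides, and which RNA its reads came from was not determined. The netrin receptor NEO1 (47.6 and 13.4 CPM), the ferroxidase HEPH (9.06 CPM in the control library), the membrane serine protease TMPRSS2 (22.6 and 6.50 CPM) and the nectin PVRL3 (14.5 and 4.04 CPM) had log2 differences from -1.62 for PVRL3 to -1.76 for NEO1. APOL1 (67.4 and 21.6 CPM), the mucin-type glycosyltransferase GALNT5 (16.5 and 4.81 CPM) and IGFBP2 (31.1 and 9.67 CPM) each had a log2 difference of -1.59. The astrocyte gene GFAP was also among the 52 lower genes. Of 41 listed genes typical of oligodendrocytes, astrocytes or neurons, a set chosen after their values were seen, all 41 were lower in the HOXC10 library, with a median log2 difference of -0.60 over the 34 genes at 1 CPM or more. Every listed gene reached at least 1.02 CPM in 1 of the libraries. Members below that in the HOXC10 library, such as MOG (1.20 and 0.307 CPM), were listed through the control library alone and could only be lower. For any other gene below 1.02 CPM in 1 library, the direction was likewise fixed by the listing.

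The title of the series raises proliferation and migration, which gene lists fixed in advance address at the RNA level. Proliferation genes did not differ together. Of 28 measured G1/S and DNA replication genes, 14 were higher and 14 lower in the HOXC10 library, with a median log2 difference of -0.0017 and a mean of 0.06. The replication clamp PCNA (280 and 438 CPM), the GINS subunit GINS2 (26.6 and 41.7 CPM) and thymidylate synthase, TYMS (37.1 and 52.2 CPM), were higher, and the polymerase subunit POLA1 (41.8 and 31.6 CPM) was lower. Of 30 G2/M and mitosis genes, 21 were higher, with a median of 0.10 at percentile 97.0 of random lists matched on expression, just inside the limits. The mitotic kinase CDK1 (238 and 317 CPM) and BIRC5 (123 and 159 CPM) were higher, and CENPF (297 and 176 CPM) and MKI67 (400 and 298 CPM), which have long transcripts, were lower. The G2/M median lay above the upper limit when a trend with expression level was removed or when genes with a mean of at least 20 CPM were used, and further inside the limits with a trend with transcript length (percentile 90.4) or GC content (93.4) removed or by its mean of 0.05 (82.8).

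Among lists bearing on migration, genes of integrins and focal adhesion stood apart, on the lower side. Of 22 measured members, 21 were lower in the HOXC10 library, with a median log2 difference of -0.30 at percentile 0 of the matched random lists. The hyaluronan receptor CD44 had 55.2 and 31.4 CPM, and the integrin subunits ITGB4 and ITGA2 and the laminin chain LAMB3 had log2 differences of -0.68, -0.67 and -0.51. Of 9 mesenchymal genes, 6 were higher, among them S100A4 (15.2 and 28.3 CPM), vimentin, VIM (4.85 and 7.16 CPM), and TAGLN (334 and 422 CPM), while THY1, which neurons also express, was lower (2.22 and 0.870 CPM). The mesenchymal median was 0.21 (percentile 91.5). Of 22 epithelial genes, 16 were lower, with ELF3 (345 and 235 CPM), DSP (518 and 371 CPM) and KRT19 (687 and 502 CPM) lower and KRT7 (4.73 and 8.80 CPM) higher, and the median was -0.09 (percentile 11.8). Extracellular proteases and their inhibitors had a median of -0.11 (percentile 9.59), with TIMP2, MMP15 and PLAUR lower beside MMP1, at log2 differences of -1.22, -0.71 and -0.61. With a transcript length trend removed, the mesenchymal list lay above the limits (percentile 98.6), but with median coding transcript length it lay inside them (percentile 94.4). The protease list lay below the limits with either length measure (percentiles 2.39 and 2.12) or with its mean of -0.33 in place of the median (percentile 0).

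In all, 8 of the 32 lists with at least 5 measured members stood apart. For lists of genes drawn at random, the limits alone would give 1.6. Members of a list may vary together between cultures, and that spread was not measured. The 1.6 is therefore not the number expected without an effect of HOXC10. The lists of cytosolic ribosomal proteins, nuclear respiratory chain genes and p53 targets lay on the higher side. All 49 cytosolic ribosomal protein genes were higher, with a median log2 difference of 0.44 (percentile 100) and RPS12 (814 and 1295 CPM) and RPL37 (637 and 1010 CPM) at the top. Of 33 nuclear genes of oxidative phosphorylation, 26 were higher, with a median of 0.30 (percentile 100), among them NDUFA4 (171 and 261 CPM) and COX7A2 (115 and 169 CPM). With a transcript length trend removed the ribosomal median was 0.17, or 0.36 with median coding transcript length, at percentile 100 with either. The respiratory chain median was 0.06, inside the limits (percentile 93.9), or 0.22 and above them (99.98) with median coding transcript length. Of 24 p53 target genes, 22 were higher, with a median of 0.27 (percentile 100), among them the death receptor FAS (8.09 and 14.4 CPM), the stress-response gene SESN1 (24.1 and 35.6 CPM), TP53INP1 (21.4 and 30.9 CPM) and CCNG1 (182 and 260 CPM).

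Several genes of differentiated gastric and intestinal epithelium were lower in the HOXC10 library. The gastric aspartic protease CTSE had 1081 and 439 CPM, and the mucin MUC1 had 49.2 and 20.3 CPM. The gastric mucosa list had only 5 measured members, of which 3 were lower, CAPN8 included (1.77 and 0.921 CPM). SOX2 was higher (10.2 and 15.8 CPM). The median log2 difference of the list was -0.53 (percentile 0.14), which is the value of CAPN8, a low gene. With 0.921 CPM in the HOXC10 library, CAPN8 was listed through the control library alone and could only be lower. The median and percentile of this list therefore rest on a gene whose direction was fixed by the listing. All 8 intestinal epithelium genes were lower, with a median of -0.40 (percentile 0.04), among them the galectin LGALS4 (31.1 and 11.8 CPM) and the cadherin CDH17 (345 and 174 CPM), and also MUC13 (51.5 and 33.2 CPM) and the transcription factor HNF4A (99.3 and 73.3 CPM). Of 27 interferon-stimulated genes, 19 were lower, with a median of -0.20 (percentile 0.08) and log2 differences of -0.94 for DDX60, -0.93 for OAS1, -0.88 for OAS2 and -0.67 for OAS3. Of 10 genes of fatty acid synthesis, 9 were lower, with a median of -0.23 (percentile 1.55), among them ELOVL6 (67.3 and 49.6 CPM), ACLY (291 and 224 CPM), ACACA (113 and 90.7 CPM) and FADS2 (2.28 and 1.54 CPM). The fatty acid list lay inside the limits when a trend with transcript length (percentile 8.03) or GC content (percentile 4.84) was removed or at a mean of at least 20 CPM (percentile 3.83), though not with median coding transcript length (percentile 0.27), and the gastric (median -0.19) and fatty acid lists both lay inside them with log2(CPM + 5).

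**Figure D2:**
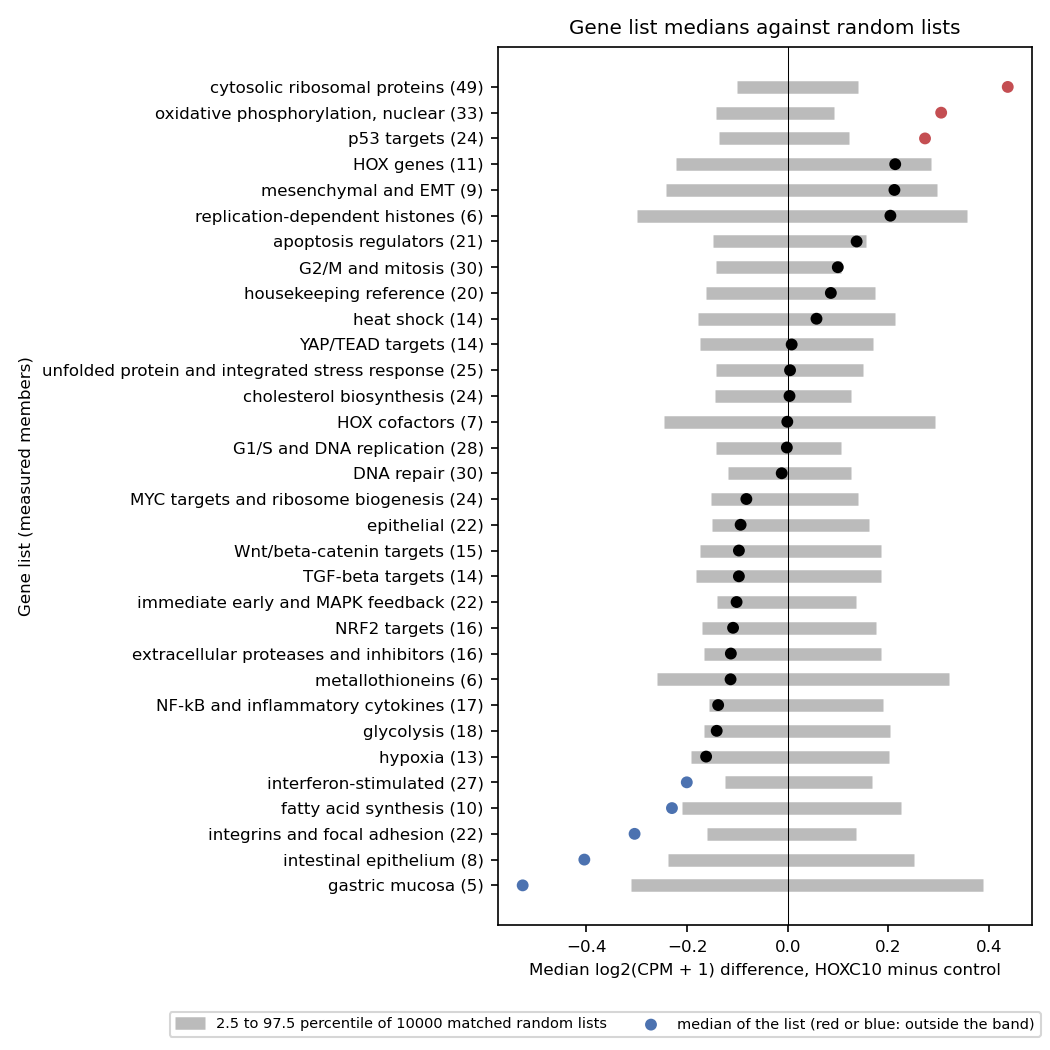
Median log2(CPM + 1) difference, HOXC10 minus control, of each of the 32 evaluated gene lists (points, number of measured members in parentheses), with the range between the percentile limits of 10000 matched random lists as grey bands. The 3 red points lie above their bands, led by ribosomal proteins at 0.44, and the 5 blue points lie below theirs, down to gastric mucosa at -0.53.

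The medians of the other 24 lists lay inside the limits, running from -0.16 to 0.21. Of 11 other HOX genes, 7 were higher in the HOXC10 library (median 0.21, percentile 92.3), among them HOXB9 (28.6 and 46.0 CPM), HOXB6 (22.2 and 33.6 CPM) and HOXB7 (0.798 and 1.89 CPM). HOXB7 was listed through the HOXC10 library alone and could only be higher. HOXB13 was lower (log2 difference -0.57), and none of the 11 passed 2-fold on the log2(CPM + 1) scale. Of 7 HOX cofactor genes, 3 were higher, PBX3 (11.3 and 14.6 CPM) among them, and 4 were lower. Of 14 targets of YAP and TEAD, 7 were higher, with a median of 0.01 inside the limits and a mean of 0.24 above them (percentile 99.8), and ANKRD1 and CYR61 (35.7 and 75.9 CPM) were over 2-fold higher. The immediate early genes EGR1 (115 and 57.3 CPM), FOS (57.7 and 35.0 CPM) and JUNB (54.7 and 34.9 CPM) were lower, though 7 genes of their list of 22 were higher. That list lay inside the limits (median -0.10, percentile 8.80). Glycolysis genes had a median of -0.14 (percentile 5.20), with hexokinase HK1 at 28.4 and 9.67 CPM and the neuronal enolase ENO2 at 2.91 and 1.33 CPM. With the length trend removed the immediate early and glycolysis lists lay below the limits, at percentiles 0.06 and 0.05, but with median coding transcript length the immediate early list lay inside them (2.83) and glycolysis below (0.27). The glycolysis list also lay below the limits with the mean in place of the median (percentile 0.07) or with a trend with expression level removed (percentile 1.00). Among stress-response genes TRIB3 (1.03 and 3.79 CPM) was over 2-fold higher, in a list of 25 with a median of 0.0047.

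Medians of the remaining lists were also small. They were 0.20 for 6 replication-dependent histone genes, which was -0.12 with the length trend removed and 0.15 with median coding transcript length, 0.14 for apoptosis regulators, 0.09 for reference housekeeping genes, 0.06 for heat shock genes with a mean of -0.0048, 0.0036 for cholesterol biosynthesis and -0.01 for DNA repair with a mean of 0.02. On the lower side they were -0.08 for MYC targets and ribosome biogenesis, -0.10 for TGF-beta targets, -0.10 for Wnt targets, -0.11 for NRF2 targets, -0.11 for metallothioneins, -0.14 for inflammatory cytokines and -0.16 for hypoxia. Some of these lay outside the limits under 1 setting: MYC targets with the length trend removed (percentile 1.64, but 8.33 with median coding length), hypoxia with median coding length (0.475, but 6.02 with the longest transcript), NRF2 targets by their mean (1.72) and apoptosis regulators with a trend with expression level removed (97.8). The Wnt inhibitor DKK1 (383 and 644 CPM) was higher and the receptor EPHB2 (44.0 and 23.9 CPM) lower. The cholesterol genes IDI1, INSIG1, SC5D and MSMO1 had log2 differences from 0.58 for MSMO1 to 0.63 for IDI1. Lists of fibroblast, leukocyte and endothelial genes had 4, 4 and 1 measured members and were not evaluated, and no mitochondrially encoded gene of the list was measured. Of the fibroblast, leukocyte and endothelial members, 3, 4 and 1 were lower in the HOXC10 library, with medians of -0.34, -0.36 and -0.42.

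The difference between the libraries followed transcript length. Over genes with a mean of at least 5 CPM, the Spearman correlation across genes of the log2 difference with annotated transcript length was -0.42, and genes are not independent replicates. The tenth of genes with the shortest transcripts (median 1135 nucleotides) had a median log2 difference of 0.29, and the tenth with the longest (median 9472.5 nucleotides) had -0.18. Ribosomal protein genes (median 1171 nucleotides) and respiratory chain genes (1268 nucleotides) lay at the short end, and integrin genes (5382.5 nucleotides) at the long end. With the trend removed, the integrin median was -0.21 (percentile 0.06) and the p53 target median 0.19 (percentile 99.95).

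**Figure D3:**
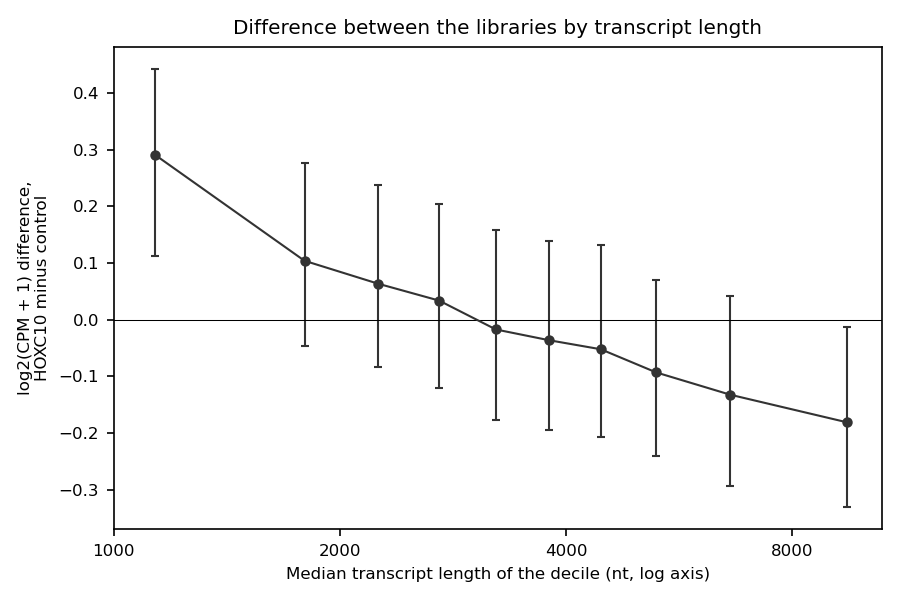
Log2(CPM + 1) difference, HOXC10 minus control, by deciles of annotated transcript length (nucleotides, log axis), with the median of each decile as points and its quartiles as bars. The medians run from 0.29 in the shortest decile to -0.18 in the longest.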

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

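Of the 15 alternatives, 10 were planned and 5 were chosen after seeing the data, namely recovered-read ratios, the trends with transcript length (by longest or median transcript) and GC content, and leaving out brain genes. HOXC10 and CST1 were higher in the HOXC10 library under every setting run on them. The CST1 log2 difference of 1.37 was 1.03 with the transcript length trend removed and 1.28 with the median transcript length trend removed, and lay within its counting interval under the others. HOXC10, at 3.21, was 1.45 with log2(CPM + 5) and 6.69 from recovered reads, since a larger pseudocount shrinks the difference of a low gene.

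The counts of 26 higher and 52 lower genes were 15 and 29 with log2(CPM + 5), 41 and 81 with no filter on level, 11 and 25 at a mean of at least 20 CPM, 269 and 228 at 1.5-fold, and 10 and 12 at 3-fold; apart from what the other pseudocount, filter or size itself selects, the cause was not tested. Without the brain sets 51 genes were lower. Of the 24 genes with the largest differences, 12 were shared at a mean of at least 20 CPM, a filter that itself removes those below that level. Of 191 values of the 24 genes under the alternatives, 0 changed sign. The 24 genes were picked from these data for their large differences. An unchanged sign was therefore all but certain and is no check of them. The number of lists standing apart ran from 6 to 12, and 6 to 8 of the original 8 were kept. For CST1 the cause was not tested.

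No paired analysis was possible because each group has 1 library, and for the same reason leaving out a library was not possible. Depth limits low genes most: HOXC10 rests on 1 control read.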

Other observations

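The tests of gene families, of copies and of brain RNA were chosen only after the result was seen, as were the families; the tests of trends with length and GC content were set before their results were seen. All 5 listed CEACAM genes, cell adhesion proteins related to the PSG family, were lower in the HOXC10 library under every scaling run, 3 of them with a counting interval below 1. Intervals that leave out 1 are common at these depths. Of 20 reference housekeeping genes, 11 had an interval above 1 and 5 had an interval below 1. CEACAM6 had 120 and 55.3 CPM, CEACAM5 9.98 and 3.27 CPM, and the summed ratio was 0.477 (0.448 to 0.508). CEACAM19 (1.20 and 0.870 CPM) was listed through the control library alone and could only be lower. Of 7 listed HOXB genes, 6 were higher under every scaling run, with a summed ratio of 1.52 (1.41 to 1.63). HOXB7 (0.798 and 1.89 CPM), which is among the 6, was listed through the HOXC10 library alone and could only be higher. KLK8 (2.17 and 6.19 CPM) and KLK6 (20.9 and 33.7 CPM), secreted serine proteases, were higher, and KLK1 was not (1.48 and 1.28 CPM).

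Of 19 listed SNHG genes, which host small nucleolar RNAs and were not placed among random lists, 18 were higher in the HOXC10 library, 12 of them with a counting interval above 1, among them SNHG6 (17.4 and 33.9 CPM). Such intervals were also common among the housekeeping genes, as given above. SNHG20 (0.969 CPM in the control) and SNHG21 (0.912 CPM) were listed through the HOXC10 library alone and could only be higher. SNHG22 (0.819 CPM in the HOXC10 library) could only be lower. With the transcript length trend removed, 16 of the 19 were higher, with a median log2 difference of 0.27 in place of 0.47, and median coding length gives no value for them. All 10 listed S100A genes were higher, but 9 were with a trend with expression level or median transcript length removed, and 5 were with the length trend removed.

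One pattern is the spread of the gene lists along transcript length, for which a library difference that acts by length is a candidate explanation. With the trend in annotated length removed, the ribosomal protein and integrin lists lay at percentiles 100 and 0.06 of matched random lists. The ribosomal median was then 0.17, or 0.36 with median transcript lengths, in place of 0.44. An annotated length need not be that of the expressed transcript, and RPL37 had 7686 nucleotides against a list median of 1171. A length effect is therefore not excluded as the source of what remained. A GC content trend left the ribosomal list at percentile 100. For the respiratory chain the explanation cannot be told apart from a difference in the cells, since the list lay at percentile 93.9 with the longest transcripts and 99.98 with median transcript lengths. An effect of HOXC10 on these lists stays open and untested with 1 library per group.

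A different pattern is the lower level of brain genes, for which a small amount of brain RNA in both libraries, more of it in the control, may be an explanation. The myelin gene MBP had 1315 and 723 reads (ratio 0.494) and the astrocyte gene GFAP 34.3 and 16.4 CPM, and the oligodendrocyte, astrocyte and neuron medians all lay below percentile 2.5, the highest at 1.71. The sets were chosen after their values were seen, and some low members were listed through the control library alone. These percentiles are therefore no independent support for brain RNA. With the trend in annotated transcript length removed, the median log2 difference over the 3 sets was -0.58 in place of -0.60. The trend in annotated length therefore accounted for little of it. The percentile stayed at 0, which is no further evidence for sets chosen after their values were seen. An annotated length need not be that of the expressed transcript, so an effect of length is not excluded. A single source at 1 ratio could not supply all reads either, since 9 of 41 genes left out the summed ratio of MBP and GFAP (0.489), where chance allows 5, and 8 of these, CNP and UGT8 among them, lay above it. Only ALDOC of these genes is also in a fixed list, the AGS level of each gene is not known here, and a true difference between the cells stays open.

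Another pattern is the higher level of genes with close copies, where reads moved between copies could mislead. For the PSG genes the summed ratio was 3.60 (3.34 to 3.90), and for CST1 with CST4 it was 2.57 (2.48 to 2.67), which a move of reads among the listed copies would leave at 1. CST4 reads per CST1 read were 2.42% in the control and 1.82% in the HOXC10 library, a ratio of 0.751 (0.582 to 0.974). The ratio would be 1 if all CST4 reads were misassigned CST1 reads in a fixed share. A constant level of CST4 with such a share added would also give a ratio below 1. Misassigned reads as the source of the CST4 difference therefore stay open. Copies that the table does not list were not analysed here. An effect of HOXC10, a difference between cultures and, for CST1, part of the length trend (1.03 with it removed) stay open.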
